A study of Mus musculus with 74 samples.

How the data were processed

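The series holds 74 mouse samples: 40 ChIP samples, 6 ChIP input samples and 28 RNA libraries. Per the labels, the DN3 ChIP cells were bone-marrow progenitors cultured on OP9-DL1 stroma, which presents a Notch ligand and drives T-lineage development, for 7 days, then treated with 120 nM 4-hydroxytamoxifen and kept for 5 more days. Bcl11bKO cells lost the gene in this treatment and WT_DN3 cells kept it. DN3 denotes pro-T cells past commitment. Scid.adh.2c2 is a pro-T-like cell line that carried a control hairpin (shControl) or one against Bcl11b (shBcl11b). For RNA, lineage-depleted marrow cells were cultured for 7 days, given retroviral guide RNAs, kept for 7 more days and sorted for CD45, CD25 and the guide vector's CFP, without mature-lineage markers. Groups were sgControl and sgBcl11b with 4 libraries each, and sgChd4, sgMta1_2, sgRest, sgRing1a_b, sgLSD1, sgRunx1, sgId2, sgZbtb16, sgBcl11b_Id2 and sgBcl11b_Zbtb16 with 2 libraries each. DN3 ChIP had 2 samples per antibody and genotype. The Scid.adh.2c2 ChIP had 1 sample per antibody and hairpin, so nothing there measures spread between replicates. The labels do not state whether replicates were separate cultures, so every p-value measures only the spread between samples, which may be technical.

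The expression values are RPKM, which the authors made with HOMER from exon counts against mm9 and condensed to 1 line per gene, per the file headers. How strand was treated is not stated, so values of antisense or overlapping genes, such as Dgkeos and Mir147, may hold reads of their neighbours. The values move in whole-read steps for the stated gene length, which gave each library's total: 26.29 to 40.32 M reads (M, mega). At these totals every low value fell within 0.15 reads of a whole number. Reads on genes numbered 20.11 to 31.0 M per library, and 10751 to 11469 genes reached 1 RPKM. The peak signal is the deposited tag count, which HOMER scales to a fixed number of tags per library. The peak score is the authors' HOMER score. It has no fixed range and was used only to rank or filter peaks within a list. Each of the 16 DN3 lists came from both replicates, per the labels. The depth of the DN3 ChIP libraries is unknown. The 8 Scid.adh.2c2 lists were called from 1 library each against input at a false discovery rate of 0.001 and at least 4-fold over input and local signal, and held 23049611 to 32233862 tags per library. All their listed peaks had a tag count of at least 15. The submitters' processing notes name Bowtie 1.1.1, HOMER, Trimmomatic 033, STAR 2.4.0, RSEM 1.2.25 and edgeR 3.6.8. The notes give no HOMER version. Peak and gene positions are on mm9 (NCBIM37), from the files.

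Both RPKM tables, a cofactor table of 20 libraries and a double-guide table of 16, hold the same 4 sgControl and 4 sgBcl11b libraries. The plan had treated them as separate experiments, so the comparison across experiments was replaced. Genes were called in sgBcl11b replicates 1 and 2 and then read in replicates 3 and 4. The numbering of the submitters' read directories placed the libraries in 4 series. Series A held replicate 1 of the cofactor groups. Series B held replicate 2 of those groups and both sgLSD1 libraries. Series C held replicate 3 of sgControl and sgBcl11b with replicate 1 of the double-guide groups, and series D held replicate 4 with replicate 2 of those groups. Pairing was checked by correlating each library's departures from its group mean, across genes. Among cofactor libraries, 44 of 58 pairs with the same replicate number and 51 of 58 in the same series exceeded a correlation of 0.1. In the double-guide table all 32 same-series pairs did, the lowest at 0.23, against 24 of 32 same-number pairs. The text therefore gives, for each comparison with calls, the count of genes called with library series as a replicate block as well, and names the list calls that this block ended or reversed.

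Values were analysed as log2(RPKM + 1) in limma 3.58.1 under R 4.3.3, with a trended prior and all groups of a table in 1 fit. Genes needed at least 1 RPKM in at least 2 libraries. Fold changes on this scale understate changes of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, 12189 in the cofactor table and 12034 in the double-guide table. All tests were two-sided. Up to 10 called genes per direction were named for sgBcl11b in the cofactor table and for both double guides, and up to 5 elsewhere. They were taken by size of change among genes with a mean of at least 2 RPKM in the higher group, no overlap between the libraries of both groups, and a symbol other than those of predicted genes, clones or antigen-receptor segments. Guide targets and list members were named whatever their result. The 16 gene lists were T-lineage identity, NK and innate lymphoid, stem and progenitor, myeloid, B-lineage, stromal (OP9-like), mast and basophil, gamma-delta T, DP and later T, neuronal REST-type, Polycomb developmental, p53 response, interferon response, proliferation, E-protein/Id and pre-TCR axis, and subunits of the NuRD, PRC1, CoREST and REST complexes. The list of complex subunits also held Runx1, which is not a subunit of these complexes. All lists, the filter, the pseudocount, the tests and the overlap rule were fixed before the data were examined. Lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. This made 187 tests across the contrasts, adjusted as 1 family. fry was used where a list was read in other libraries than those that chose it. Overlap between contrasts that share sgControl was set against 100 simulations of unchanged groups, against independent lists, and against a fit that gave each contrast its own controls. On simulated data with 200 changed genes, 4-fold changes were recovered for 90.9% of genes with 4 libraries against 4 and for 87.9% with 2 against 4. Changes of 2-fold were recovered for 73.1% and 62.7%, and 1.5-fold changes for 40.3% and 23.9%. In the fit for sgBcl11b_Id2 against sgBcl11b these shares were 95.5%, 58.2% and 37.3%. A shifted list was called and no other list was. The simulated genes varied independently and without series effects, so this does not show how list calls behave where genes vary together. Unchanged genes called numbered 15, 2 and 14 in the 3 simulated contrasts.

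A peak was retained when a peak of the other list overlapped it by at least 1 bp, and a reference peak was at a Bcl11b site when it overlapped a WT_DN3 Bcl11b peak. Intervals for shares are exact 95% binomial (Clopper-Pearson) intervals. Intervals for shares and odds ratios cover counting error only. Loss at Bcl11b sites was compared with loss at other sites by Fisher's exact test, and by Mantel-Haenszel odds ratios over 4 quartiles of the peak score or 20 strata. Genes near peaks had a peak within 10 kb of the transcription start site. That family held 50 tests, adjusted together. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for peaks and plots.

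The alternatives run were a pseudocount of 0.1, no filter, quantile normalization, a fit of only the groups compared, each library left out, replicate number or library series as a block, single pairs of series, the estimated correlation, controls split by series, an overlap of at least 50% of the shorter peak, the top-scoring part of each list, lists of equal length, and a 50 kb window. The series block, the 20 strata and the split controls were added after the files were seen. Raw reads and the mm9 sequence were not used here, so peaks were neither recalled nor searched for motifs, and the 6 input samples enter only through the authors' peak calls.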

Results

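The samples address which proteins Bcl11b, a zinc-finger transcription factor of T-lineage commitment, needs or brings to chromatin in pro-T cells, and which genes it keeps active or silent. Peak lists covered Bcl11b and 7 other proteins in DN3 cells with and without Bcl11b, and 4 of these proteins in the Scid.adh.2c2 line. RNA came from 28 libraries in 12 guide groups, and the depth of each library is given with the methods.

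In Bcl11bKO cells the Bcl11b list shrank from 26091 peaks to 182, Mta2 lost most of its peaks, and Rest lost many of its own. All 182 peaks were also in the WT_DN3 list, which left 0.698% of WT Bcl11b peaks (exact 95% binomial interval 0.6 to 0.806%). Mta2, a subunit of the NuRD chromatin-remodelling complex, went from 13914 to 5291 peaks, and 27.7% (27.0 to 28.5%) of the WT peaks were retained. Rest, a repressor of neuronal genes, went from 6549 to 3660 peaks with 50.4% (49.2 to 51.6%) retained. The NuRD ATPase Chd4 kept 70.3% of 23074 peaks, the deacetylase Hdac2 67.2% of 33087, the Polycomb protein Ring1b 73.4% of 15587, the demethylase LSD1 74.3% of 28297, and Runx1 68.8% of 33129. Every list but Bcl11b's also held peaks seen only in Bcl11bKO cells: 9.86% of the Rest list and 31.3% of the LSD1 list, the lowest and highest shares. When the longer list was shortened by score to the length of the other, the retained share was 50.0% for Mta2, 61.5% for Bcl11b, whose shortened list held 182 peaks, 69.7 to 76.0% for the other 5 proteins and 80.1% for Rest, then the highest. The DN3 lists give no depth, so a peak absent from a list may lie just under its threshold.

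**Figure D1:**
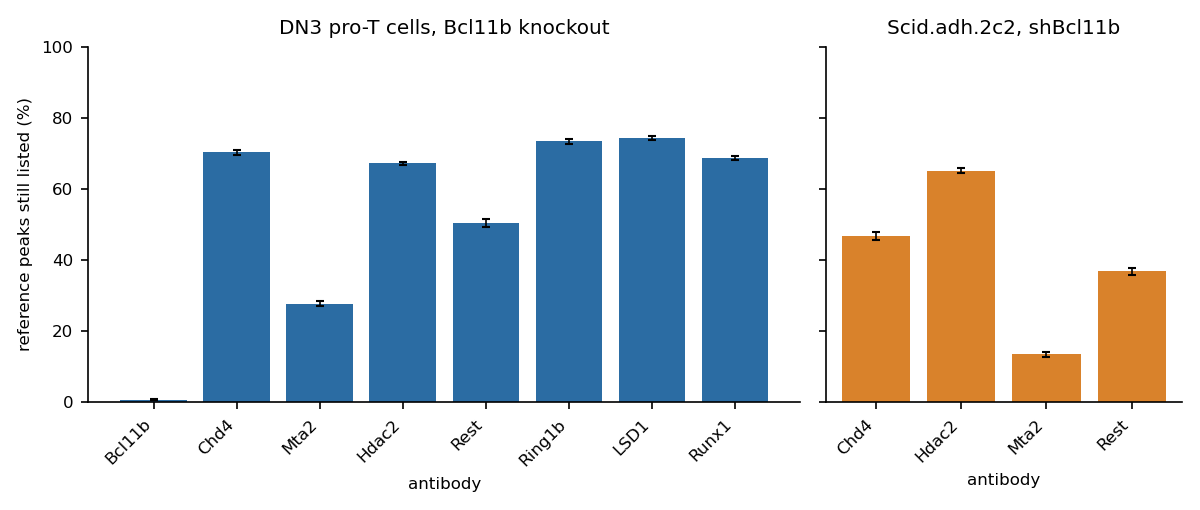
Share of reference peaks still listed after loss of Bcl11b, in percent, for each antibody in DN3 cells (left) and Scid.adh.2c2 cells (right); bars are shares and error bars exact 95% binomial intervals. Bcl11b itself keeps 0.698% and Mta2 the least of the other proteins in both systems, 27.7% and 13.5%.

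Over the whole lists Mta2 and Rest also kept the smallest shares in the cell line. With the hairpin against Bcl11b, Mta2 kept 13.5% (12.7 to 14.2%) of 7486 peaks and Rest 36.8% (35.7 to 37.8%) of 8051. Chd4 kept 46.8% of 7906 peaks and Hdac2 65.1% of 20423. Each list came from 1 library, so no replicate spread exists here. At equal list lengths Mta2 kept 39.7%, Chd4 51.0%, Rest 69.5% and Hdac2 74.5%, so the place of Rest depended on list length. The share of tags inside peaks also fell, from 3.86 to 1.60% for Mta2, from 8.51 to 3.51% for Rest, from 4.22 to 3.76% for Chd4 and from 9.47 to 7.27% for Hdac2. At the 4637 Mta2 sites that WT_DN3 and shControl cells shared, 2489 were lost in both systems, an odds ratio of 5.04 (4.26 to 5.97). Shared sites of Rest and Hdac2 were also lost together, at 7.06 and 8.59. Among sites of like score the value was 1.33 (1.09 to 1.62) for Rest, 4.85 for Hdac2, 2.46 for Chd4 and 4.71 (3.84 to 5.77) for Mta2.

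At the 26091 Bcl11b sites of WT_DN3 cells, Mta2 went down most between genotypes, and Rest, which lay on few sites, went down about as much in proportion. Mta2 lay on 48.3% of these sites in WT_DN3 and 13.1% in Bcl11bKO cells, and Rest on 12.2% and 3.48%. Runx1 lay on 90.3 and 71.2%, Hdac2 on 83.5 and 64.7%, LSD1 on 79.5 and 68.7%, Chd4 on 64.6 and 60.2%, and Ring1b on 49.1 and 43.0%. Mta2 peaks on a Bcl11b site were lost in 74.0% of cases and those elsewhere in 55.8%, an odds ratio of 2.25 (2.01 to 2.53, Fisher's exact p 4.4e-41). For Rest the shares were 73.9 and 26.5%, an odds ratio of 7.87 (7.05 to 8.79). All the others were lost less often on Bcl11b sites: the odds ratio was 0.313 for Chd4, 0.478 for Hdac2, 0.524 for Ring1b, 0.430 for LSD1 and 0.301 for Runx1. Peaks on Bcl11b sites had higher scores, and high-scoring peaks were lost less often. Among peaks of like score, in 20 strata, Mta2 reached 4.03 (3.49 to 4.66) and Rest 3.18 (2.72 to 3.71). Hdac2 then reversed to 1.91 (1.80 to 2.04), LSD1 to 1.18 (1.11 to 1.26) and Runx1 to 1.13 (1.06 to 1.21). Chd4 stayed under 1 at 0.535 and Ring1b at 0.854. For Hdac2, LSD1 and Runx1 these are averages over scores at which the direction differed. Of the lowest score quartile, Hdac2 lost 71.0% of peaks on Bcl11b sites and 58.9% elsewhere, LSD1 55.9 and 49.3% and Runx1 64.6 and 60.3%. In the highest quartile the order turned, at 2.76 and 11.7% for Hdac2, 2.56 and 13.2% for LSD1 and 2.87 and 9.02% for Runx1. Over 4 score quartiles Runx1 was 1.02 (p 0.56). In Scid.adh.2c2 cells Mta2 stood at 0.671 (0.571 to 0.789) and at 0.722 with strata, the opposite side of 1 from DN3 cells, but at 1.13 (0.863 to 1.47) with lists of equal length. Chd4 gave 0.676 there and 0.727 with strata, Hdac2 0.348 and 0.794. The Rest value of 1.52 reversed to 0.222, and to 0.891 (0.735 to 1.08) with lists of equal length. These cell-line ratios used the DN3 Bcl11b list, since the line had none of its own.

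**Figure D2:**
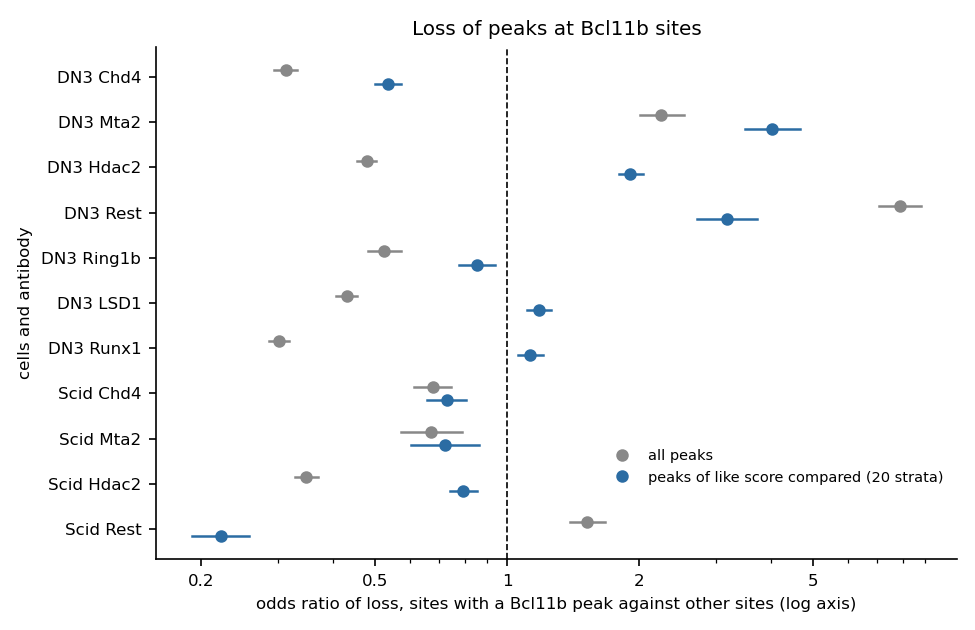
Odds ratio of peak loss at sites with a WT_DN3 Bcl11b peak against other sites, on a log axis, for each antibody in DN3 and Scid.adh.2c2 cells; grey points use all peaks, blue points compare peaks of like score, and lines are 95% intervals. In DN3 cells Mta2 (2.25 and 4.03) and Rest (7.87 and 3.18) lie above 1 both ways, and Hdac2 moves from 0.478 to 1.91.

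Id2 and Zbtb16 both carried Bcl11b peaks. Id2, an inhibitor of the E proteins that drive T and B development, had a Bcl11b peak 67 bp upstream of its start (chromosome 12, 25780899 to 25781149, score 296, rank 9669 in the list). Hdac2, LSD1 and Runx1 overlapped it in WT_DN3 cells; in Bcl11bKO cells LSD1 and Runx1 remained, Hdac2 was absent and an Mta2 peak was listed. Zbtb16, which encodes the innate-lymphocyte factor PLZF, held 6 Bcl11b peaks inside the gene (chromosome 9, 48462402 to 48644050), with scores of 117 to 324. Mta2 overlapped 4 of the 6 in WT_DN3 cells and 0 in Bcl11bKO cells. Counted over the gene with 10 kb on either side, Mta2 peaks went from 4 to 0 in DN3 cells and from 4 to 0 in Scid.adh.2c2 cells, where Chd4 went from 4 to 1 and Hdac2 from 6 to 4. Over that stretch Chd4 had 4 peaks in each DN3 genotype, Hdac2 4 and 7, LSD1 4 and 8, and Runx1 8 and 8. The highest Bcl11b scores, 1505 and 1504, were at neighbouring sites in Mocos (chromosome 18, 24831294 to 24831544 and 24830684 to 24830934), followed by 1427 on chromosome 8 (19784522 to 19784772) near 4930467E23Rik, and all 3 remained in the Bcl11bKO list.

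Transcript levels of the targeted genes lay above or below the control level depending on the guide. They do not check the guide labels, since a guide cut need not lower a transcript. Against the sgControl library of the same series, Bcl11b RNA stood at 2.37, 1.87, 1.88 and 2.02 in the 4 libraries labelled sgBcl11b, at 1.86 and 1.85 in sgBcl11b_Id2 and at 1.69 and 1.78 in sgBcl11b_Zbtb16. Chd4 stood at 1.33 and 1.54 in its libraries, Rest at 1.59 and 1.39 and Runx1 at 1.93 and 2.31. Mta1 stood at 0.693 and 0.670, Mta2 at 0.677 and 0.726, Kdm1a, which encodes LSD1, at 0.728 and 0.758, Ring1 at 0.815 and 0.924 and Rnf2 at 0.734 and 0.850. Id2 stood at 0.982 and 0.890 in sgId2 and Zbtb16 at 1.82 and 1.13 in sgZbtb16. In series C and D, Id2 stood at 12.9 and 9.52 in sgBcl11b, 7.12 and 5.59 in sgBcl11b_Id2 and 8.06 and 6.53 in sgBcl11b_Zbtb16. Zbtb16 in these groups stood at 109 and 53.8, at 59.1 and 24.9, and at 77.9 and 33.5. Both transcripts were thus lower than in sgBcl11b under either double guide. Of the targets under their own guide only Mta1 passed, at -0.58 ± 0.08 on the log2 scale (SE, limma adjusted p 0.0044), and that call ended without either sgMta1_2 library, in series A and B alone and when only the compared groups were fitted. The Bcl11b change of 1.00 ± 0.41 did not pass (limma adjusted p 0.13), but did with library series as a replicate block (1.3e-06), as did Chd4 (0.0096), Mta2 (2.1e-04), Kdm1a (0.024) and Runx1 (5.7e-05) under their own guides.

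With the Bcl11b guide CD3 transcripts fell, and innate-lymphoid genes and the mast and basophil genes Mcpt8 and Cpa3 rose. Cd3g, a chain of the T-cell receptor complex, fell by 4.09 ± 0.24 on the log2 scale (SE, n = 4 against 4, limma adjusted p 2e-07), from 510 ± 53.4 (SD) to 29.5 ± 6.81 RPKM. Its neighbours on chromosome 9 followed, with Cd3d down from 104 ± 49.7 to 7.85 ± 2.22 RPKM and Cd3e down from 43.7 ± 14.8 to 3.62 ± 1.57. Zbtb16 rose by 4.68 ± 0.31, from 0.908 ± 0.132 to 54.2 ± 29.2 RPKM (limma adjusted p 3.5e-07). Id2 rose by 2.75 ± 0.26, from 11.6 ± 0.548 to 92.5 ± 44.5 RPKM (limma adjusted p 9.9e-06).

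The fit called 881 genes higher and 806 lower of 12189 tested, 290 and 177 of them at least 2-fold, at a median standard error of 0.158. Tnni1, a muscle troponin, led the risers at 4.78 ± 0.20 (limma adjusted p 8.7e-09, 0.102 to 30.7 RPKM). The signalling adaptors Tyrobp and Fcer1g, which pair with NK and Fc receptors, rose from 5.06 to 115 and from 8.75 to 158 RPKM. The basophil protease Mcpt8, the Notch-family ligand Dlk1, the growth factor Fgf3, the scavenger receptor Cd163l1, the myosin Myo1e and the HMG-box factor Tox2 completed the group, at 3.51 to 4.33. Cd163l1 reached 421 ± 131 RPKM. The ketogenic enzyme Hmgcs2 fell by 2.45 and Tpd52, a vesicle-traffic protein, by 2.39. The receptor Gpr132, the noncoding Dgkeos, the signalling brake Cd5, the NAD-cleaving Bst1 and Mir147 fell by 2.18 to 2.25. With library series as a replicate block the counts were 2495 higher and 2928 lower. With series A and B alone 407 genes passed, and Cd163l1, Hmgcs2, Gpr132, Dgkeos and Mir147 did not.

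Of 35 ways to part the 8 libraries 4 against 4, the real one gave 1687 calls and the highest other 45. In the double-guide table, whose fit shares these 8 libraries, the real split gave 1922 calls and the highest other 1242. Libraries of the same series varied together, so the 35 splits are not fully interchangeable and do not by themselves exclude chance. Among the 8 splits that parted all 4 same-series pairs, too few for a share under 0.05, no other gave a call in either table. That second fit called 967 genes higher and 955 lower of 12034, and 5265 with the replicate block. Without sgControl 1 it called 3041, and with only the sgControl and sgBcl11b libraries fitted 1268. Replicates 1 and 2 alone called 269 genes higher and 138 lower; in replicates 3 and 4, 403 of these 407 (99.0%) went the same way and 355 were called again. With the replicate block 2063 genes were called in both. Fold changes from both pairs correlated at r = 0.908 across 11956 genes, which are not independent replicates.

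**Figure D3:**
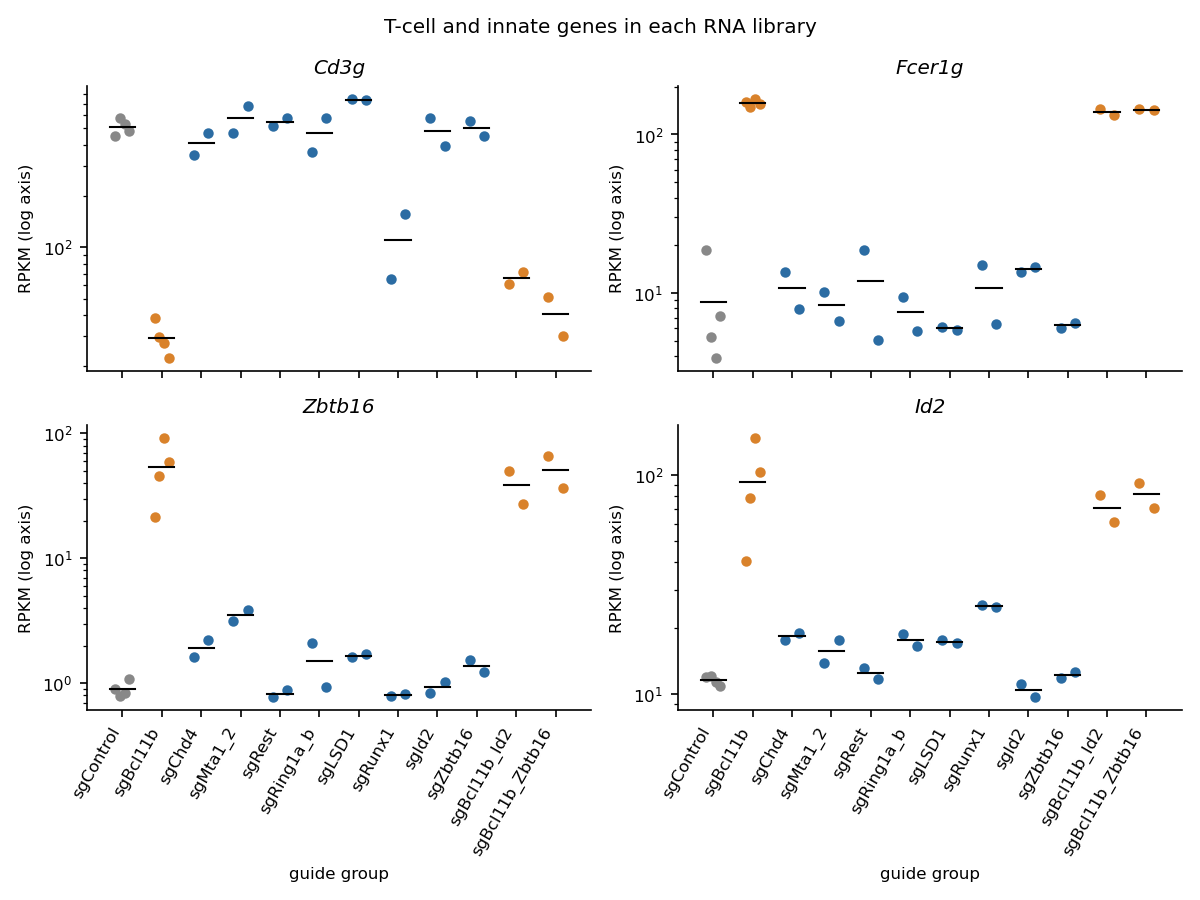
RPKM of Cd3g, Fcer1g, Zbtb16 and Id2 on log axes in each RNA library by guide group; points are libraries (n = 4 for sgControl and sgBcl11b, n = 2 otherwise), black lines group means, and orange marks groups with a Bcl11b guide. Every library with a Bcl11b guide lies apart from all sgControl libraries for all 4 genes, and sgRunx1 lowers Cd3g to a mean of 111 RPKM.

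In the NK and innate lymphoid list 18 of 28 measured genes rose in sgBcl11b and 0 fell (21 and 1 adjusted over the list alone), with a median log2 change of 1.45 (camera adjusted p 2.7e-14). The estimated correlation ended the list's call (p 0.0031, adjusted 0.20). Il2rb, the shared IL-2 and IL-15 receptor chain, rose by 2.78 ± 0.59 and Klrd1, an NK receptor, by 1.83. Il2rb lost its call in series A and B alone. Gzma was between 203 and 619 RPKM in sgControl and between 1712 and 2227 RPKM in sgBcl11b libraries. Nkg7 went the other way, as the lowest list member in each series, at -0.77, -0.68, -0.52 and -1.06 in A to D. It was between 45.8 and 105 RPKM in sgControl and between 30.9 and 61.6 RPKM in sgBcl11b libraries. For this list the real split gave the smallest camera p of the 35 (2.9e-16), and the smallest other, 2e-14, came from a split that also parted all 4 same-series pairs. The T-lineage identity list went down with a median of -0.61 (camera adjusted p 8.6e-04), a call that the estimated correlation ended (p 0.26): 10 of 30 genes fell and 4 rose (12 and 4 adjusted over the list alone). Cd3g, Cd3d, Cd3e, Cd5, Cd6, Dntt, Lat, Zap70, Rag2 and Trat1 fell, whereas the early T factors Gata3 (1.37) and Tcf7 (0.43) rose with Il2ra (0.29) and Themis (1.58). A camera p as small came from 7 of the 35 splits (smallest other 1.5e-05, real 7.8e-05), so chance cannot be excluded for this list. Of 17 interferon response genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), at a median of -0.28 (camera adjusted p 6.4e-04). The estimated correlation ended that call (p 0.0063, adjusted 0.20), and 4 of the 35 splits gave a camera p as small (smallest other 7.6e-07, real 4.8e-05), so chance cannot be excluded here either. Among these genes the sensor Ifih1 fell by 0.92 ± 0.11, Usp18 by 0.93 ± 0.19 and Oas2 by 0.90 ± 0.21; the last pair lost their calls in series A and B alone. The mast and basophil list rose at a median of 1.06 (camera adjusted p 0.028): Mcpt8 and Cpa3 rose of 3 genes, Cpa3 from 150 to 315 RPKM. The estimated correlation (p 0.015, adjusted 0.40) and the replicate block (adjusted p 0.24) each ended that list's call. As many as 7 lists were called in another split of the 8 libraries against 4 in the real one, so chance cannot be excluded for the number of lists. The double-guide table called the T-lineage list (2 higher, 12 lower; camera adjusted p 6.7e-04), the NK and innate lymphoid list (20 higher, 0 lower; 9.9e-14) and the interferon list (0 higher, 8 lower of 16; 2.3e-04). None of these calls remained with the estimated correlation (p 0.26, 0.0055 and 0.0050; adjusted 0.20 for the last pair). Adjusted over the list alone the counts were 3 and 13, 21 and 1, and 0 and 8. There 3 lists were called in the real split and up to 7 in another.

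The other 12 lists did not shift in sgBcl11b. The stem and progenitor list had 3 members higher and 2 lower of 19 (4 and 2 adjusted over the list alone). Its median was -0.15 where camera pointed up (adjusted p 0.97). Flt3, a progenitor cytokine receptor, rose by 1.11 to 1.43 RPKM. Kit rose by 1.13 (limma adjusted p 0.023), a call that ended without sgControl 1 or 3 or sgBcl11b 2, 3 or 4. The B-lineage list had 1 higher and 3 lower of 7 (camera adjusted p 0.14), with the coactivator Pou2af1 up from 1.41 to 25.3 RPKM. The gamma-delta T list had 3 higher and 1 lower of 7 (0.76), the lower one Sox13, with a median of -0.11 where camera pointed up. The myeloid list had 2 higher and 1 lower of 12 (0.78), the lower one the lysozyme Lyz2 at -1.79. The stromal list had 0 higher and 1 lower of 16 (0.80), the DP and later T list 1 and 1 of 12 (0.90) and the p53 list 1 and 1 of 19 (0.96), at a median of -0.03 where camera pointed up. No member passed in the proliferation (0.82), neuronal REST-type (0.93) or Polycomb lists (0.97). In the E-protein/Id and pre-TCR list (0.33) Id2 rose, and Cd3e, Id3 (-1.26) and Rag2 (-0.87) fell. Adjusted over the list alone, 2 rose and 3 fell there, 1 and 0 in the p53 list and 3 and 4 among complex subunits. Of 36 genes in the list of complex subunits, which also held Runx1, 1 rose and 4 fell (0.90). Chd4 rose by 0.47 and Chd3 fell by 0.83. The Chd3 call ended without sgControl 3 or 4 or sgBcl11b 1. Flt3, Pou2af1, Sox13, Lyz2, Id3, Rag2, Chd4 and Chd3 did not pass in series A and B alone.

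**Figure D4:**
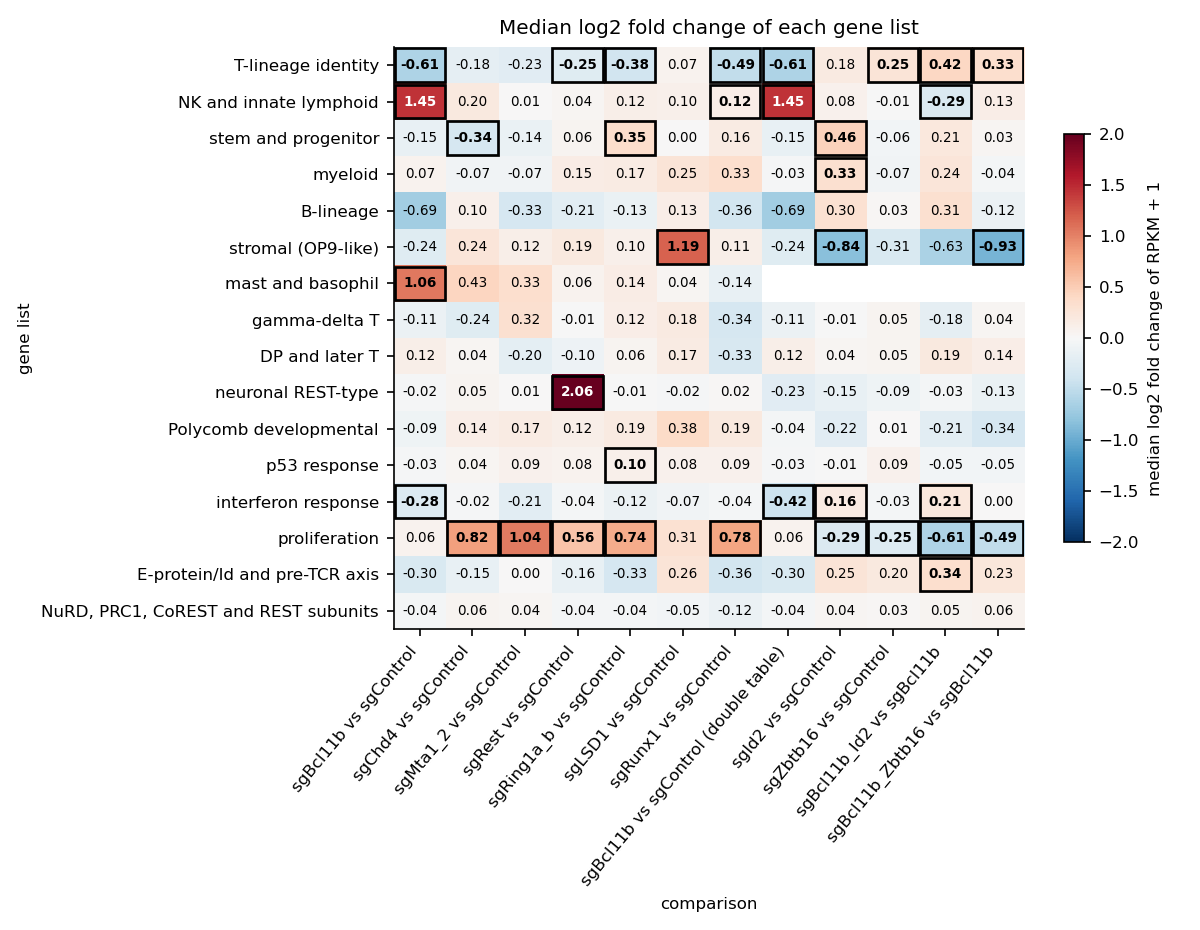
Median log2 fold change of RPKM + 1 over the measured genes of each list (vertical) in each comparison (horizontal); boxed bold values passed camera at the preset correlation. The NK and innate lymphoid list stands at 1.45 in sgBcl11b and the neuronal REST-type list at 2.06 in sgRest.

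Neuronal genes rose with the Rest guide. Unc13a, a protein of synaptic-vesicle priming, rose by 3.19 ± 0.16 on the log2 scale (n = 2 against 4, limma adjusted p 4.8e-08), from 0.182 to 10.2 ± 4.25 RPKM. The neurofilament Ina rose from 0.270 to 9.81 RPKM, the granule protein Chga from 0.0308 to 3.61 (limma adjusted p 4.8e-08), Unc5a, a netrin receptor, by 2.25 and Rundc3a by 2.69. In all 22 genes rose and 0 fell (36 and 0 with the replicate block), at a median standard error of 0.193, and 123 genes had an unadjusted p under 0.05. Lrp11 also rose, a call that ended without either sgRest library, with a pseudocount of 0.1, in series A and B alone and with only the compared groups. The neuronal REST-type list had 5 of 8 genes higher (7 adjusted over the list alone) and a median of 2.06 (camera adjusted p 6.6e-60). It was the only list of the 36 called over all contrasts to keep its call with the estimated correlation (adjusted p 1.4e-07). Preset-correlation camera also put the T-lineage list at -0.25 (adjusted p 0.026, estimated-correlation p 0.41) and the proliferation list at 0.56 (1.6e-05, estimated-correlation p 0.29). Both ended with the replicate block, at adjusted p 0.99 and 0.22, the proliferation list at a median of -0.04. Series A and B alone gave 11 calls, without Rundc3a, and a fit of only the sgControl and sgRest libraries gave 10.

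With the Runx1 guide CD3 transcripts fell too, while Zap70 went the other way than in sgBcl11b. Cd3e fell by 2.41 ± 0.30 (n = 2 against 4, limma adjusted p 0.0014), from 43.7 to 7.14 RPKM, Cd3g from 510 to 111 ± 64.7 RPKM and Cd3d by 1.90. Zap70, the kinase downstream of CD3, rose by 2.02 ± 0.28 here and fell by 0.82 in sgBcl11b. The tetraspanin Tspan32 rose by 2.85 ± 0.18, from 5.35 to 44.3 RPKM, and the adaptor Ldlrap1 by 2.22. The adhesion protein Cd2 and the tetraspanin Cd81 rose by 2.33. The integrin Itgae, the sialic-acid enzyme Cmah and the receptor partner Ramp3 fell by 2.82, 2.80 and 2.62. A total of 57 genes rose and 82 fell, with 1507 at an unadjusted p under 0.05, and 474 and 747 with the replicate block. The count depended on single libraries: 252 without sgControl 1, 83 without sgControl 4, 27 without sgRunx1 1 and 63 without sgRunx1 2. With only the sgControl and sgRunx1 libraries fitted no gene passed, and series A and B alone gave 43. Cd2 and Cd81 were not called without sgControl 3 or sgRunx1 1, Cd81 without sgControl 4, Cmah without any of sgControl 2 to 4, and Cmah, Itgae and Cd81 without sgRunx1 2. In series A and B alone Cd2, Cd81 and Cmah were not called. Zap70, Cd3d, Itgae, Cmah and Ramp3 were not called without sgRunx1 1. The T-lineage list had 1 higher and 3 lower (2 and 4 adjusted over the list alone) at a median of -0.49 (-0.21 with the block; camera adjusted p 0.0062, estimated-correlation p 0.34). The NK and innate lymphoid list had 2 higher and 1 lower (4 and 1 adjusted over the list alone) at 0.12 (0.22 with the block; 0.034, estimated-correlation p 0.24), and the proliferation list stood at 0.78 (8.6e-04, estimated-correlation p 0.40; no longer called with the block, at 0.11 and adjusted p 0.05). Id2 was 25.3 RPKM against 11.6, not called (limma adjusted p 0.15; 0.015 with the replicate block). Bcl11b was 24.7 RPKM against 59.7 (0.36; 8.1e-04 with the block).

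With the Mta1 and Mta2 guides Sult5a1 and Card10 rose and the progenitor factor Spi1 fell. The sulfotransferase Sult5a1 rose by 1.98 ± 0.20 (n = 2 against 4, limma adjusted p 7.2e-04) and the scaffold Card10 by 1.93 ± 0.27, from 0.396 to 4.26 RPKM. Lipg, Mpzl2 and Arsi rose by 1.69 to 1.91. Spi1, which encodes PU.1 and is shut off at commitment, fell by 1.51 ± 0.32, from 11.8 ± 3.72 to 3.62 ± 2.13 RPKM (limma adjusted p 0.049). Gpr25, Ifit1bl1, Slc28a2 and Sgsh fell by 1.21 to 1.51. Zbtb16 stood at 3.52 ± 0.497 RPKM against 0.908, not called (limma adjusted p 0.17) but called with the replicate block (0.012). A total of 46 genes rose and 47 fell, with 1447 at an unadjusted p under 0.05, and 731 and 933 with the replicate block. Leaving out either sgMta1_2 library left 4 calls, ending all those named but Sult5a1. Without sgControl 1, 2, 3 or 4 there were 155, 29, 35 and 18 calls. Without sgControl 2, 3 or 4 the named calls other than Sult5a1, Card10 and Arsi ended, and Arsi's ended without any control library. Series A and B alone gave 5 calls, a pseudocount of 0.1 gave 57, and no gene passed when only the sgControl and sgMta1_2 libraries were fitted. The proliferation list stood at 1.04 (camera adjusted p 9.6e-07, estimated-correlation p 0.24), with 0 members called; with the block it stood at 0.41 with 19 called higher. In the T-lineage list 0 rose and 1 fell (camera adjusted p 0.31).

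Few genes were called with the Chd4, Ring1a/b or LSD1 guides. With Chd4 targeted, Cox6b2, a testis form of a respiratory-chain subunit, rose by 3.26 ± 0.23 (n = 2 against 4, limma adjusted p 9.8e-06), from 0.572 to 14.1 RPKM, and the linker histone H1fx by 2.42 ± 0.20, from 2.32 to 16.7 RPKM. Tesc, Card10 and Ccl27b rose by 1.40 to 2.03, and the death ligand Tnfsf10 fell by 0.59. In all 16 rose and 1 fell, with 632 at an unadjusted p under 0.05, and 126 and 60 with the replicate block. Leaving out sgControl 1, 2 or 4 gave 10, 11 and 10 calls and leaving out sgChd4 1 or 2 gave 6 and 4. Tesc, Card10, Ccl27b and Tnfsf10 each lost their calls without sgChd4 2, and all but Card10 without sgChd4 1. All 4 did so in series A and B alone, Tesc and Card10 without sgControl 1, 2 or 4, Tnfsf10 without sgControl 2, 3 or 4, and Tesc without sgControl 3. Without the filter 65 genes passed, with a pseudocount of 0.1 there were 9, with series A and B alone 5 and with only the groups compared 1. Its stem and progenitor list stood at -0.34 (camera adjusted p 0.0064, estimated-correlation p 0.16) and its proliferation list at 0.82 (0.19 with the block; 4.2e-06, estimated-correlation p 0.27), with 0 members called.

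With Ring1a and Ring1b targeted, 1 gene passed, the Notch and BMP target Hey1, which rose by 2.10 ± 0.24 (n = 2 against 4, limma adjusted p 0.0056) from 0.160 to 4.43 ± 3.15 RPKM. A further 653 genes had an unadjusted p under 0.05. Cdkn2a, the classical Polycomb target, stood at 11.5 ± 13.4 RPKM against 0.295 and did not pass (limma adjusted p 0.43), nor did the p53 targets Perp and Zmat3. All 3 passed without sgRing1a_b 2, when 11 genes were called. The replicate block gave 2 calls and the fit without a filter 12; series A and B alone and the fit of only the groups compared gave 0. Camera put the T-lineage list at -0.38 (-0.18 with the block; adjusted p 0.0016, estimated-correlation p 0.28), stem and progenitor at 0.35 (0.0048, estimated-correlation p 0.14), p53 at 0.10 (0.0016, estimated-correlation p 0.066) and proliferation at 0.74 (0.08 with the block; 1.4e-04, estimated-correlation p 0.34). Adjusted over the list alone, 3 p53 genes and, in the Polycomb list (camera adjusted p 0.15), 1 gene, Cdkn2a, passed. With LSD1 targeted 4 genes rose and 0 fell, with 716 at an unadjusted p under 0.05. Amica1, an adhesion molecule, rose by 1.95 ± 0.18 (n = 2 against 4, limma adjusted p 5.4e-04), Aldh3b1 from 3.63 to 14.8 RPKM, and the Hedgehog effector Gli1 by 0.88. With the replicate block 29 rose and 4 fell. Aldh3b1 and Gli1 lost their calls without sgControl 1, 3 or 4 or either sgLSD1 library, Gli1 also without sgControl 2, and those fits called 1 gene each, or 2 without sgControl 2. No filter gave 48 calls, quantile normalization 2, the groups compared alone 1, and a pseudocount of 0.1 or series A and B alone 0. Both sgLSD1 libraries fell in series B. The stromal list stood at 1.19 (camera adjusted p 0.0022, estimated-correlation p 0.32), but at -0.15 with the block (adjusted p 0.86).

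Genes called under Runx1 or Mta1/2 guides overlapped those of Bcl11b in the same direction. Of the Runx1 calls 66 were also called in sgBcl11b with the same sign, against 9.54 for independent lists, and 11 with the opposite sign. Tspan32 rose by 1.97 and Ramp3 fell by 1.57 in sgBcl11b, as in sgRunx1. Of the Mta1/2 calls 45 were shared with the same sign, against 6.43 for independent lists, and 5 with the opposite. Chd4 shared 2 (1.22 for independent lists) and Rest 0 (1.59), with 3 of the Rest genes called in the opposite direction; Ring1a/b and LSD1 shared 0. With the replicate block Runx1 shared 751 (276 for independent lists), Mta1/2 967 (374), Chd4 102 (40.2), LSD1 12 (6.90), Rest 2 (7.37) and Ring1a/b 0. The contrasts share their sgControl libraries, and 100 simulations of unchanged groups gave a covariance of 0.0056. Shared calls numbered 0 there, which is no measure for the overlap, since calls are rare where no group is changed. The observed covariance was 0.0649 for Mta1/2, 0.0628 for Runx1, 0.0429 for Chd4, 0.0353 for Ring1a/b, 0.0210 for Rest and 0.0034 for LSD1. The LSD1 value depended on series B, which held both its libraries, and was 0.0260 with the block. As Pearson correlations without the block, Mta1/2 stood at 0.384, Runx1 at 0.348 and Chd4 at 0.315, each against 0.241 in the simulations. Ring1a/b, at 0.25 against 0.24, lay near its simulated value. Rest, at 0.194 against 0.241, and LSD1, at 0.026 against 0.199, lay below theirs. When each contrast had its own controls, Runx1 shared 14 genes at a covariance of 0.0496 and Mta1/2 shared 2 at 0.0506. Those fits gave 0.0245 for Chd4, 0.0187 for Ring1a/b, -0.0012 for Rest and -0.0243 for LSD1.

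No gene was called with a guide against Id2 or Zbtb16 alone. limma called 0 of 12034 in sgId2 and in sgZbtb16, with 217 and 45 genes at an unadjusted p under 0.05, at a median standard error of 0.174. In sgId2 camera put the stem and progenitor list at 0.46 (adjusted p 0.0020, estimated-correlation p 0.17), the myeloid list at 0.33 (0.044, estimated-correlation p 0.062), interferon at 0.16 (0.0063; estimated-correlation p 0.021, adjusted 0.50) and the stromal list at -0.84 (-0.47 with the block; 0.021, estimated-correlation p 0.39). The proliferation list stood at -0.29 (0.031, estimated-correlation p 0.56) and reversed to 0.38 with the replicate block (2.9e-08). In sgZbtb16 the T-lineage list stood at 0.25 (0.0016, estimated-correlation p 0.29; adjusted p 0.81 at 0.04 with the block). Proliferation stood at -0.25 (0.025, estimated-correlation p 0.54) and reversed to 0.40 with the block (1.1e-17), so neither sign holds for it in sgId2 or sgZbtb16. Without the filter 2 genes passed in sgId2.

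With an Id2 guide added to the Bcl11b guide, the genes lower in sgBcl11b stood part of the way back, with no single gene called. Cd5 stood at 5.89 ± 0.78 RPKM in sgBcl11b_Id2 against 1.78 ± 0.424 in sgBcl11b (1.32 ± 0.22 on the log2 scale, n = 2 against 4, limma adjusted p 0.25). Cd3e stood at 9.40 against 3.62 RPKM, Dntt, the template-free DNA polymerase of receptor assembly, at 449 against 212, and the cytotoxic protease Gzmb at 11.1 against 26.2. limma called 0 genes, with 436 at an unadjusted p under 0.05 and a smallest adjusted p of 0.133. The replicate block called 39 higher and 10 lower, Cd3e among them (adjusted p 0.033). Without sgBcl11b 1 there were 10 calls, without the filter 5, and with series C and D alone 7, with Cd5 among them. Of the 138 genes lower in sgBcl11b replicates 1 and 2, 130 (94.2%) were above their level in sgBcl11b replicates 3 and 4, against 51.2% of other genes (camera p 6.9e-25, estimated-correlation p 0.0075), at a median of 0.29 where sgBcl11b had moved them by -0.99. Against no change limma fry gave p 0.0024. Of the 269 higher genes 207 (77.0%) moved back, against 48.8% (camera p 2.2e-16, estimated-correlation p 0.10), at a median of -0.14, and fry gave p 0.10. The T-lineage list stood at 0.42 (0.22 with the block; camera adjusted p 1.7e-06, estimated-correlation p 0.14) with 2 members higher when adjusted over the list alone, and the NK and innate lymphoid list at -0.29 (6.2e-04, estimated-correlation p 0.10). Interferon stood at 0.21 (3e-04), a call that the estimated correlation ended (p 0.0056, adjusted 0.20), the E-protein/Id and pre-TCR list at 0.34 (0.014, estimated-correlation p 0.15) and proliferation at -0.61 (2.6e-04, estimated-correlation p 0.37), but at 0.06 with the block (adjusted p 0.98).

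With a Zbtb16 guide added instead, the genes lower in sgBcl11b stood lower than with the Id2 guide added (limma fry p 0.013 for the difference). No difference was shown for the higher genes (limma fry p 0.53). Gzmb stood at 2.26 against 26.2 RPKM (-3.04 ± 0.61 on the log2 scale, n = 2 against 4, limma adjusted p 0.40), and the chemokines Ccl5 at 18.7 against 3.79 and Xcl1 at 17.6 against 5.76 RPKM. The last pair passed with the replicate block (adjusted p 0.048 each). limma called 0 genes, with 247 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0541. The block called 10 higher and 2 lower. Without sgBcl11b 1 there were 4 calls, without the filter 15, with series C and D alone 9 and with only the groups compared 1. Of the 138 lower genes 103 (74.6%) moved back, against 48.9% of other genes, and of the 269 higher genes 171 (63.6%), against 51.1%. Against other genes camera gave p 9.3e-06 and 5.5e-07, which the estimated correlation took to 0.14 and 0.29, and against no change fry gave 0.21 and 0.28. Within the fit of series C and D, 6 of these genes were called in the direction of return over both double guides. With the block there were 253, from longer lists of genes, and with a pseudocount of 0.1 there were 2. The T-lineage list stood at 0.33 (0.14 with the block; camera adjusted p 1.4e-04, estimated-correlation p 0.21) and the stromal list at -0.93 (-0.53 with the block; 0.028, estimated-correlation p 0.41). Proliferation stood at -0.49 (0.0028, estimated-correlation p 0.45) and reversed to 0.12 with the replicate block (0.0079). The NK and innate lymphoid list did not shift (0.22), with 3 higher and 1 lower when adjusted over the list alone. The interaction of both guides gave 0 calls for Id2 and for Zbtb16, with 61 and 54 genes at an unadjusted p under 0.05 and a median standard error of 0.247. The block called 1 gene in the Zbtb16 interaction, and series C and D alone called 2.

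**Figure D5:**
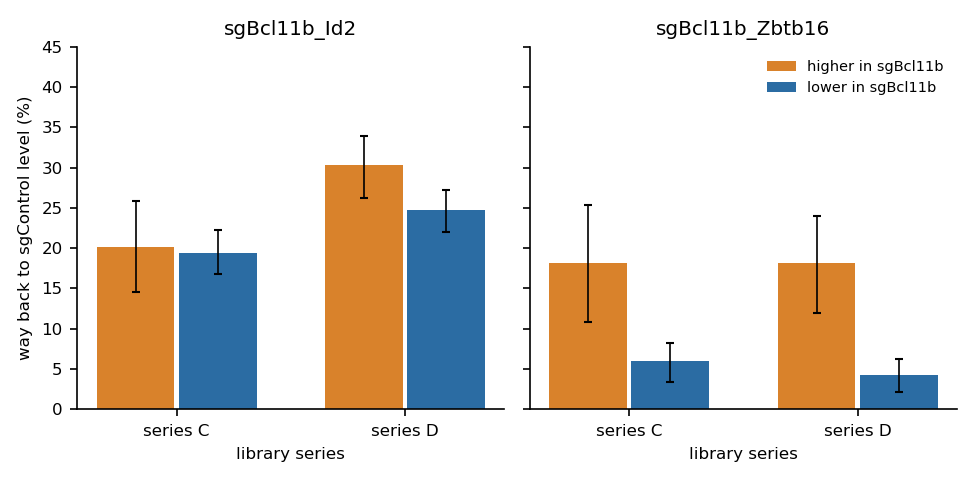
Share of the way from the sgBcl11b level back to the sgControl level of the same series, in percent, for 269 genes higher and 138 lower in sgBcl11b replicates 1 and 2; bars are ratios of sums over genes in 1 library each of series C and D, and error bars 95% bootstrap intervals over genes. sgBcl11b_Id2 goes back by 19.4 to 30.3% in both sets, and sgBcl11b_Zbtb16 by 18.1 and 18.2% for higher genes and by 6.0 and 4.2% for lower genes.

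Genes that fell in sgBcl11b lay near sites where Runx1, Hdac2 and LSD1 were lost with Bcl11b. Of 806 lower genes 25.8% had a Runx1 peak on a Bcl11b site, absent from Bcl11bKO cells, within 10 kb of their start, against 11.2% of 10502 unchanged genes (odds ratio 2.76, Fisher's exact p 4.1e-28, adjusted over 50 tests 2e-26). For Hdac2 the share of lower genes was 24.2% (2.60, p 4.8e-24, adjusted 1.2e-22) and for LSD1 18.9 and 9.04% (2.34, p 2e-16, adjusted 1.7e-15). Lost Ring1b (1.72), Chd4 (1.67) and Mta2 peaks (1.34, p 6.2e-05, adjusted 1.6e-04) followed, and lost Rest peaks were rarer near lower genes (0.629) and near higher genes (0.588). Genes that rose lay near peaks seen only in Bcl11bKO cells. Ring1b-only peaks lay near 20.0% of 881 higher genes and 10.1% of unchanged ones (2.23, p 1e-16, adjusted 1e-15). The odds ratio was 2.07 for LSD1 (30.5 and 17.5%), 2.06 for Runx1 (27.1 and 15.3%), 1.88 for Chd4, 1.72 for Hdac2 and 1.53 for Mta2 (p 0.022, adjusted 0.035), and 1.11 for Rest (adjusted p 0.77). Such peaks of Ring1b (1.73), Runx1 (1.37) and LSD1 (1.31, p 0.0026, adjusted 0.0050) were also more frequent near lower genes. Chd4-only peaks near lower genes passed with the calls of the replicate block (1.18, unadjusted p 0.0029). The Mta2 value did not pass with a 50 kb window or with the calls of the replicate block. Those block calls also made lost Hdac2 (1.42), Runx1 (1.41), LSD1 (1.31) and Chd4 peaks (1.22) more frequent near higher genes. A Bcl11b peak itself lay near 86.4% of unchanged genes, 87.1% of lower genes (1.06, adjusted p 0.67) and 83.9% of higher genes (0.82, p 0.042, adjusted 0.066). The 50 kb window gave 1.61 for lower genes (p 0.014, adjusted 0.023). Genes were not matched for expression or for number of peaks.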

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

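The tests weighed in this part were chosen after the results were seen. Among 84 groups of 4 libraries, 7 held a library far from the other 3, where chance gives about 1 in 20 groups, or 4.2. All 7 lay in sgControl, 4 in replicate 1 and 3 in replicate 3. Outside these 84 groups such libraries also occurred in sgBcl11b. In its replicate 1, Sgsh stood at 7.42 RPKM (others 5.40 to 5.57), Mta2 at 100 (113 to 115) and Cox6b2 at 0.461 (0.219 to 0.249). In its replicate 2, Ccl27b stood at 0.159 RPKM (others 0). In sgControl 1, Mcpt8 stood at 3.28 RPKM (others 0.066 to 0.213), Ldlrap1 at 6.96 (4.43 to 4.49), Mpzl2 at 5.84 (2.12 to 2.53) and Ring1 at 10.0 (16.7 to 17.3). In sgControl 3, Itgae stood at 48.0 RPKM (11.5 to 12.1), Ramp3 at 120 (45.3 to 53) and Cd3d at 178 (73.0 to 86.1). Other guide groups with libraries in that series and another were then compared, and their library of the same series lay on the same side in 37 of 39 comparisons, the exceptions being Mcpt8 in sgBcl11b and sgChd4. In sgId2 and sgZbtb16, Cd3d stood at 179 and 189 RPKM in series C and 54.9 and 75.4 in D. The flagged sgControl values thus follow the library series.

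The odds ratio of Mta2 peak loss at Bcl11b sites was 2.25 in DN3 cells and 0.671 in Scid.adh.2c2 cells, on opposite sides of 1. The difference between them was not tested, and with lists of equal length the value in the line was 1.13, and 0.891 for Rest. A lower yield of the ChIP after loss of Bcl11b would take weak peaks wherever they lie. In DN3 cells peaks of like score were still lost more often at Bcl11b sites, at 4.03 for Mta2 and 3.18 for Rest, which argues against yield as the whole cause there. In Scid.adh.2c2 cells the values were 0.722 and 0.222, so a lower yield may account for the losses in the line. Shared sites were lost together at 4.71 for Mta2 among sites of like score, but also at 4.85 for Hdac2 and 2.46 for Chd4. Among shared sites of like score in both systems, loss in both was more frequent on Bcl11b sites for Mta2, at 2.96 (2.08 to 4.21). The same held for Hdac2 at 1.62 (1.40 to 1.87), but not for Rest at 0.974 (0.811 to 1.17) or Chd4 at 0.567. Without regard to score, Mta2 and Rest sites were lost in both more often on Bcl11b sites, and Hdac2 and Chd4 sites less often. The direction for Hdac2 thus depended on the score strata. Loss in DN3 cells alone could give the Mta2 value, so whether a set of Mta2 sites needs Bcl11b in both stays open.

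Of the 35 splits of the 8 sgControl and sgBcl11b libraries, only the real one gave as many genes called, in either table. It gave 1687 calls against 45 at the highest other split in the cofactor table, and 1922 against 1242 in the double-guide table. Libraries of the same series varied together, so the 35 splits are not fully interchangeable and do not by themselves exclude chance. Among the 8 splits that part all 4 same-series pairs, too few for a share under 0.05, the highest other gave 0 in limma in both tables. Nor did the splits exclude chance for the number of lists: 12 of 35 splits gave at least the real 4, and 22 of 35 at least the real 3, with 7 at the highest other split in both tables. For the rise of the NK and innate lymphoid list 1 of the 35 splits, the real one, gave so small a camera p (2.9e-16). The smallest other, 2e-14, came from a split that also parts all 4 same-series pairs, and the 8 such splits are too few for a share under 0.05. Chance could not be excluded for the fall of the T-lineage list, where 7 of 35 splits gave a camera p as small (real 7.8e-05, smallest other 1.5e-05), or of the interferon list, where 4 did (4.8e-05, 7.6e-07). Among the 8 splits that part all same-series pairs, the real one gave the smallest T-lineage camera p, with another at 8.5e-05. For the interferon list, the split with 7.6e-07 was among these 8.

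The NK and innate lymphoid list rose in sgBcl11b by camera at the preset correlation, not at the estimated one (adjusted p 0.20), with 18 of 28 genes higher. Mature NK cells among the sorted cells would bring their transcripts, yet Prf1, Klrb1c, Eomes and Tbx21 reached at most 0.537 RPKM in any sgBcl11b library, where Fcer1g stood at 149 to 167, and the sort for cells without mature-lineage markers would remove such cells. Replacement of T-lineage cells by cells without such transcripts would need 94.1% other cells to give the fall of Cd3g. Yet 23 of 30 T-lineage genes fell by less than 1 log2 unit or, in 6 cases, lay above the control level. The scale understates falls of low genes, so the count of 23 is too high. Zap70 is in it, at 2.3 RPKM in sgControl and 0.783 in sgBcl11b. Il2ra encodes CD25, for which the cells were sorted, so the sort may have held its level up. Each series held 1 sgControl and 1 sgBcl11b library, so by design a difference between series could not give the rise. The lowest median within a series was 0.849. Outgrowth of a cell that keeps part of the T-lineage program and a change within cells both stay open, and either could give these values.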

How the results depend on the processing

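The series block, single pairs of series, 20 strata, split controls and the peaks outside the Bcl11bKO Bcl11b list were added after the data were seen. Where a value below moved, the cause was not tested unless stated. All alternatives chosen beforehand were run, and each gave a value. Of the counts, shares and odds ratios under these alternatives 214 stayed within their limits, 111 moved, 14 reversed, 1 gained and 2 lost its threshold. Among single genes named, leaving out 1 library kept 5351 of 5524 values on their side of the threshold, with 153 lost and 20 gained. The series block lost 0 and gained 104 of 870, a pseudocount of 0.1 lost 14, no filter lost 7 and gained 3, and quantile normalization lost 7 and gained 4. Fitting only the compared groups lost 40, series A and B alone 50 of 522, and no single gene reversed.

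With replicate number as a block, genes called went from 1687 to 4204 in sgBcl11b, from 17 to 48 in sgChd4, from 93 to 534 in sgMta1_2, from 1 to 2 in sgRing1a_b, from 4 to 11 in sgLSD1 and from 139 to 559 in sgRunx1. In the double-guide table, with only sgControl and sgBcl11b, they went from 1922 to 4538. With series as the replicate block they were 5423, 186, 1664, 2, 33 and 1221 in the same order, 36 in sgRest (22 without it), 5265 in the double-guide sgBcl11b, 49 in sgBcl11b_Id2, 12 in sgBcl11b_Zbtb16 and 1 in the Zbtb16 interaction. That block took genes called in both pairs of replicates from 355 to 2063, genes called back from 6 to 253 and the overlap with sgBcl11b from 113 to 1834. In replicates 1 and 2 alone it raised the genes called from 407 to 2353, and in 3 and 4 from 2049 to 4536. It kept 26 list calls in their direction and reversed 3, proliferation in sgId2, sgZbtb16 and sgBcl11b_Zbtb16. It ended 7 list calls and added 7: NK and innate lymphoid in sgLSD1, complex subunits in sgChd4, interferon in sgMta1_2, myeloid and interferon in sgRing1a_b, and stem and progenitor and myeloid in sgBcl11b_Id2. It changed no other list call.

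Series A and B alone gave 407 calls in sgBcl11b, 5 in sgChd4, 5 in sgMta1_2, 11 in sgRest, 0 in sgRing1a_b, 0 in sgLSD1 and 43 in sgRunx1, with fewer control libraries. Series C and D alone gave 7 in sgBcl11b_Id2, 9 in sgBcl11b_Zbtb16 and 2 in the Zbtb16 interaction. A pseudocount of 0.1 gave 9 in sgChd4, 57 in sgMta1_2, 0 in sgLSD1 and 2 genes called back. No filter gave 65 in sgChd4, 42 in sgRest, 12 in sgRing1a_b, 48 in sgLSD1, 2 in sgId2, 5 in sgBcl11b_Id2 and 15 in sgBcl11b_Zbtb16, with more genes tested. Quantile normalization gave 2 in sgLSD1. Only the groups compared gave 1 in sgChd4, 0 in sgMta1_2, 10 in sgRest, 0 in sgRing1a_b, 1 in sgLSD1, 0 in sgRunx1, 1268 in the double-guide sgBcl11b and 1 in sgBcl11b_Zbtb16, with fewer libraries to estimate the spread. Lists called went from 36 to 1 with the estimated correlation, and to 1 with the series block and the estimated correlation. Split controls took the overlap from 113 to 16.

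Leaving out 1 library at a time gave 4 to 12 calls in sgChd4, 4 to 155 in sgMta1_2, 1 to 11 in sgRing1a_b, 1 to 2 in sgLSD1, 27 to 252 in sgRunx1, 1408 to 3041 in the double-guide sgBcl11b, 0 to 10 in sgBcl11b_Id2 and 0 to 4 in sgBcl11b_Zbtb16. In sgChd4, sgMta1_2, sgLSD1 and sgRunx1 most left-out libraries moved the count more than 1.5-fold. sgChd4 had 10, 11 and 10 without sgControl 1, 2 and 4, and 6 and 4 without sgChd4 1 and 2. sgMta1_2 had 155, 29, 35 and 18 without sgControl 1 to 4 and 4 without either of its own. sgLSD1 had 2 without sgControl 2 and 1 otherwise, and sgRunx1 252 and 83 without sgControl 1 and 4, and 27 and 63 without sgRunx1 1 and 2. The value of 11 in sgRing1a_b came without its replicate 2, 3041 without sgControl 1, and 10 and 4 in the double guides without sgBcl11b 1. A lone library of a group was assumed to vary like the other groups. In sgBcl11b of the cofactor table the range was 1210 to 1886, and in sgRest 15 to 22.

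With lists of equal length, retained shares in DN3 cells were 61.5% for Bcl11b, 72.0% for Chd4, 50.0% for Mta2, 70.0% for Hdac2, 80.1% for Rest, 76.0% for Ring1b, 71.6% for LSD1 and 69.7% for Runx1. In Scid.adh.2c2 cells they were 51.0% for Chd4, 74.5% for Hdac2, 39.7% for Mta2 and 69.5% for Rest, and the odds ratio of loss reversed to 1.13 for Mta2 and 0.891 for Rest. An overlap of at least 50% of the shorter peak gave 63.9% for Chd4, 26.3% for Mta2, 64.9% for Hdac2, 69.4% for Ring1b, 72.3% for LSD1 and 67.9% for Runx1, and in the line 38.7% for Chd4, 60.7% for Hdac2, 12.3% for Mta2 and 35.3% for Rest. The top-scoring part of each list gave 66.7% for Chd4, 26.3% for Mta2, 70.2% for Hdac2, 54.7% for Rest, 74.8% for Ring1b, 76.1% for LSD1 and 70.2% for Runx1, and in the line 42.5% for Chd4, 67.4% for Hdac2 and 39.5% for Rest.

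Score quartiles reversed the odds ratio of loss at Bcl11b sites to 1.72 for Hdac2, 1.10 for LSD1, 1.02 for Runx1 and 0.266 for Rest in the line. With 20 score strata these were 1.91, 1.18, 1.13 and 0.222, and with 20 tag strata 1.89, 1.17, 1.13 and 0.198. Within the highest score quartile of DN3 cells, Hdac2, LSD1 and Runx1 peaks were still lost less often at Bcl11b sites. The odds ratio of a Bcl11b peak near higher genes went from 0.820 to 1.00 in a 50 kb window and to 0.831 without peaks of the Bcl11bKO Bcl11b list, neither under an unadjusted p of 0.05, and near lower genes from 1.06 to 1.61 in that window. The unknown depth of the DN3 ChIP limits what a missing peak shows, and 2 libraries per group limit the cofactor and double guides to larger changes.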

Other observations

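The proliferation and stromal lists followed the library series more than the guide. In sgControl the mean level of the proliferation list, in log2(RPKM + 1), was 5.869 in series A, 5.013 in B, 3.449 in C and 4.923 in D. In sgBcl11b it was 5.804, 5.127, 3.641 and 5.008. The stromal list stood at 2.715, 4.223, 2.296 and 3.607 in sgControl. Of the Bcl11b peaks still listed in Bcl11bKO cells, 182 in all, Runx1 overlapped 173 there, Hdac2 and LSD1 170 each, Ring1b 166, Chd4 151, Mta2 136 and Rest 36. All 7 of these proteins overlapped 27 of the sites.

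The tests in this part were chosen after the results were seen. Genes that had moved in sgBcl11b stood closer to the sgControl level in sgBcl11b_Id2. For the genes lower in sgBcl11b a difference between series does not account for this, since at least 86.2% went back within each series. Of the genes higher in sgBcl11b, 62.5% went back in series C and 85.1% in D, and their shift did not pass (limma fry p 0.10). A smaller share of Bcl11b-disrupted cells would take higher and lower genes back by the same share of the way, and the difference in series C was -0.8 percentage points (-7.0 to 5.7), so such dilution may be a source of the return. In series D the difference was -5.6 (-10.5 to -0.9). Loss of Id2 also stays open: the lower genes stood higher in sgBcl11b_Id2 than in sgBcl11b_Zbtb16 (limma fry p 0.013). Id2 RNA was lower than in sgBcl11b of the same series under both double guides, so its level does not separate these sources. In sgBcl11b_Zbtb16, weighed apart, the difference was -12.1 points (-19.4 to -4.3) in series C and -14.1 (-20.7 to -7.4) in D, which argues against dilution alone there. All these intervals measure spread over genes in 1 library per series, not between libraries.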
